A study of Sus scrofa with 18 samples.

How the data were processed

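The series held 18 libraries of total RNA from cells described as porcine primary kidney endothelial cells, purchased after cryopreservation at passage 5. Cells were transfected with plasmid by Lipofectamine LTX, experiments ran 24 hours after transfection, and RNA was purified with the RNeasy Plus Mini kit, per the labels' protocols. Each library took its group from the sample label alone, which gave 5 GFP control, 5 ST8Sia6 plasmid, 5 cell-cell interaction, 2 wild type and 1 KEC plus all cells library. Replicate numbers follow the order of the samples within a label, so they name a library and pair nothing.

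FastQC 0.11.5, STAR 2.7.10a, featureCounts of Subread 2.0.3 and edgeR 3.40.2 are named with build susScr11, per the submitters' processing notes. The annotation, the handling of strand and of reads with several matches, the filter on low counts and the edgeR test that was chosen are not given in the sources used here. Counts of genes whose sequences have near-identical copies, such as the SLA genes and nuclear copies of mitochondrial genes, and of genes overlapping on opposite strands are therefore uncertain. The authors' deposited tables were 2, with identical counts and identical log2 CPM in both. The counts are raw whole-number counts per gene, as deposited by the authors. The log2 values are log2 CPM and log2 fold changes computed by the authors with edgeR, per the file headers. Recomputing log2 CPM with edgeR and a prior count of 2 matched the deposited values to 4.97e-14 at most. A further score column, deposited by the authors, is a signed fold change in which a value below 1 is written as minus its inverse. Each p-value and FDR column was deposited by the authors from their own edgeR comparison. The other column, the gene length in bases, is as deposited by the authors and was not used here. No column of sample values was left unmapped to a sample.

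The tables held 15240 genes with Ensembl identifiers and versions, of which 11927 had a symbol in the authors' deposited tables, 65 more were named from a table pairing identifiers with symbols, and 3248 stayed unnamed. That table matched 11760 identifiers. A symbol shared by more than 1 gene was held by 69 genes. The smallest total count of a gene over all libraries was 23, so genes below that were not analysed here. Coordinates are those of the deposited tables. Exon, intron and UTR positions were not used here.

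Each comparison took the libraries of its 2 labels only. Genes were kept with edgeR's filterByExpr, scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3, robust fit), two-sided, at a Benjamini-Hochberg false discovery rate under 0.05. Reported CPM are TMM-scaled over all 18 libraries, and means are given with SD. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. ST8SIA6 was compared on log2(CPM + 0.5) by an exact permutation test over 252 regroupings, with a floor of 3 counts for a value of 0. Floors cover counting error only. KEC plus all cells had 1 library and no test.

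A set of 30 gene lists was fixed before the data were examined. So were the tests other than fry, the settings said below to be fixed in advance and the rule for named genes. The lists covered the sialic acid pathway, xenoantigen synthesis, interferon-stimulated genes, nucleic acid sensing, NF-kB cytokines and chemokines, endothelial adhesion and identity, MHC class I and II, complement, coagulation, costimulatory and checkpoint ligands, and mesenchymal genes. They also covered cell cycle, unfolded protein response, heat shock, p53 and apoptosis, hypoxia, cholesterol synthesis, oxidative stress, lysosome, mitochondrially encoded genes and immediate early genes, and markers of T, NK, B, monocyte, pan-leukocyte, erythrocyte and platelet, and kidney epithelial cells. Lists with at least 5 tested genes were tested against the other genes by camera with a preset correlation of 0.01, and again with an estimated correlation and by fry, which tests whether a list moves on balance in 1 direction. Adjustment over a list alone used the same unadjusted p-values.

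The named genes were ST8SIA6, then the 6 largest rises and 6 largest falls (3 and 3 for wild type) among genes with a symbol that passed, had a mean of at least 5 CPM in the higher group and did not overlap between labels. Where fewer than 6 passed, the 3 rising and 3 falling genes with the lowest p-values were added and are said not to pass. Up to 4 members of each called list (2 for wild type) with a mean of at least 1 CPM and the lowest p-values were named next, in order of the camera p, to about 30 genes. A gene that this rule took is not reported here, although counts over the genes of the rule include it.

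Other settings, fixed in advance, were RLE scaling, no filter, at least 5 CPM, DESeq2 1.42.0, limma-voom, all groups in 1 fit, an absolute log2 fold change of at least 1, each library left out in turn, and pseudocounts of 0.1 and 1 for ST8SIA6. Settings chosen after seeing the data were fits with only libraries under or over 10% mitochondrial, the mitochondrial class as a term, mitochondrial genes left out before scaling, GFP control 1 and 2 left out for their leukocyte transcripts, and mutually closest libraries of 1 label summed. The 10% limit was set after seeing the mitochondrial shares, and libraries on its sides are not groups of the study. Similarity of libraries was the chi-square per degree of freedom of their counts over genes with at least 20 counts in a pair, for 153 pairs. The authors' deposited log2 fold changes were regressed on the log2 CPM of the libraries over 10466 genes to read which libraries each comparison weighed.

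The tests were tried on simulated data with 200 changed genes per comparison. For 2-fold changes, 52.2% of changed genes were recovered in the design of ST8Sia6 plasmid against GFP control, 41.8% in that of cell-cell interaction against GFP control, 41.8% in that of cell-cell interaction against ST8Sia6 plasmid and 8.96% in that of wild type against GFP control. For 4-fold changes the shares were 86.4%, 92.4%, 77.3% and 69.7%. False calls made up 9.09%, 7.69%, 1.19% and 1.82% of the calls. The shares of 9.09% and 7.69% lay above the false discovery rate set for the tests. Each simulated count was drawn independently, so the simulated data lacked the correlation between genes of the real libraries. Between ST8Sia6 plasmid and GFP control that correlation was estimated at 0.78 for cell cycle and 0.96 for mitochondrially encoded genes. The recovered shares therefore describe the simulated data and do not give the power of the tests in the real libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.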

Results

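Gene expression was measured by sequencing total RNA from a purchased culture of porcine (Sus scrofa) cells. The labels describe them as primary kidney endothelial cells, the cells that line blood vessels. Levels of endothelial and epithelial markers are given at the end of this report. The cells had been transfected by lipid reagent with a plasmid for ST8Sia6 or with a control plasmid for GFP, a fluorescent protein. ST8SIA6 encodes a sialyltransferase, an enzyme that adds sialic acid to sialic acid already present on glycans. By their labels, 5 libraries were GFP control, 5 were ST8Sia6 plasmid, 5 were cell-cell interaction, 2 were wild type and 1 was a negative sample of kidney endothelial cells plus all cells, called KEC plus all cells here. The protocols in the labels placed the transfected cells 24 hours after transfection and spoke of 4 experiments. They also described co-culture of transfected cells with peripheral blood mononuclear cells (PBMCs) of 4 individuals. The labels did not say which plasmid the cell-cell interaction libraries had, nor which libraries came from the same experiment. The p-values therefore measured only the spread between these samples, which may be technical.

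Counts assigned to 15240 genes summed to between 14867035 and 33301008 per library. Transcripts of the mitochondrial genome took between 1.22% and 4.32% of the counts in 12 libraries and between 13.8% and 25.4% in the other 6. These 6 were ST8Sia6 plasmid 4 (17.5%) and 5 (16.7%) and cell-cell interaction 1 (19.6%), 2 (13.8%), 3 (24.3%) and 4 (25.4%), whereas cell-cell interaction 5 had 3.32%. The 6 libraries were also the shallowest, at 14867035 to 21429389 counts against 22600548 to 33301008 in the other 12. Leukocyte transcripts stood out in libraries labelled GFP control 1 and 2, where the summed level of 19 pan-leukocyte markers was 99.0 and 171 CPM (counts scaled to a common library total), against 31.2 to 34.2 CPM in GFP control 3, 4 and 5. When each library was compared with every other over all genes, 16 of the 18 libraries formed 8 pairs whose members were each other's closest library. Of these pairs, 5 shared a label and 3 did not (GFP control 5 with ST8Sia6 plasmid 1, cell-cell interaction 5 with wild type 1, and wild type 2 with KEC plus all cells 1). No pair agreed within sampling noise, the closest being wild type 2 and KEC plus all cells 1 at a chi-square of 2.31 per degree of freedom.

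ST8SIA6, the gene that the plasmid was meant to supply, was examined first in every library. Its counts did not separate the labels. The libraries labelled ST8Sia6 plasmid 1 to 5 had 59, 0, 3, 0 and 61 counts of ST8SIA6, and those labelled GFP control 1 to 5 had 0, 27, 0, 5 and 1. The highest ST8SIA6 count, 439, was in the library labelled cell-cell interaction 2, while the other 4 libraries of that label had 0, 0, 24 and 2. Wild type 1 and 2 had 1 and 0 counts and KEC plus all cells had 0. In these units the mean ST8SIA6 level was 1.02 ± 1.37 CPM in the libraries labelled ST8Sia6 plasmid (SD, n = 5), 0.242 ± 0.416 CPM in those labelled GFP control (n = 5) and 5.91 ± 12.4 CPM in those labelled cell-cell interaction (n = 5). A floor of 3 counts, which covers counting error only, corresponded to 0.0848 to 0.192 CPM. The difference in log2(CPM + 0.5) of 0.65 between ST8Sia6 plasmid and GFP control was not larger than the spread between libraries (exact permutation test, two-sided, p = 0.365, 252 regroupings), and the gene was too low to enter the genome-wide fit. The counts lie on the pig gene ENSSSCG00000011034.4 (build susScr11, chromosome 10, 43601674 to 43755140), and the labels do not give the species or extent of the coding sequence in the plasmid. Because the gene did not separate the labels, every direction given for ST8Sia6 plasmid or GFP control in this report is a direction between labels.

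**Figure D1:**
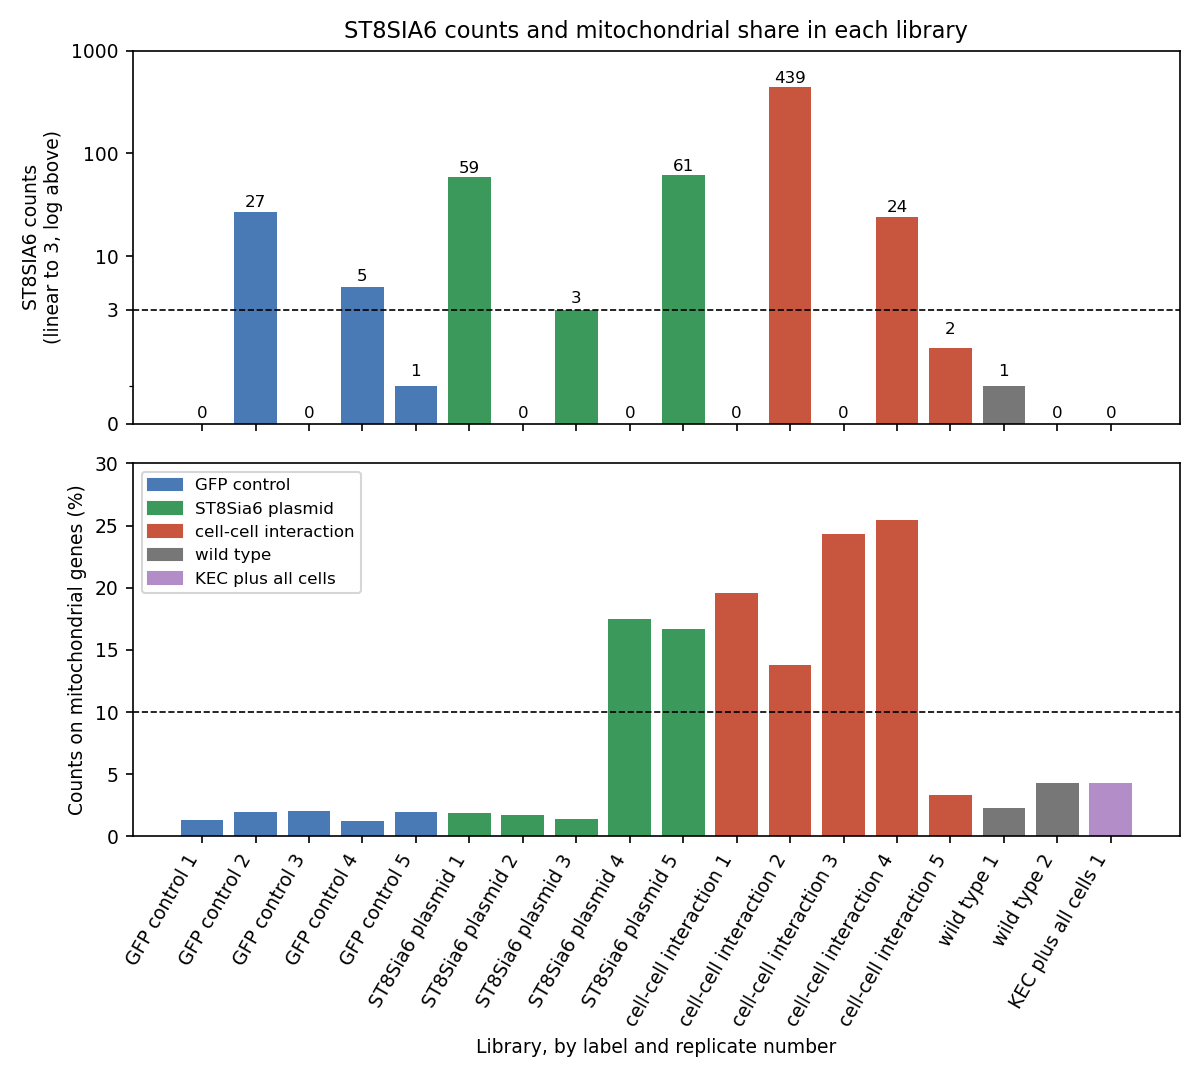
The upper panel plots the ST8SIA6 count of each of the 18 libraries (linear up to 3 counts and logarithmic above, dashed line at the floor of 3 counts), and the lower panel plots the percent of counts on mitochondrial genes with a dashed line at 10%. ST8SIA6 reached 61 counts at most under its own label and 439 in cell-cell interaction 2, and 6 libraries lay above 10% mitochondrial.

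No gene passed the threshold between the 5 libraries labelled ST8Sia6 plasmid and the 5 labelled GFP control. By its labels this comparison asks what the ST8Sia6 plasmid changes in the cells. The authors' deposited fold changes, described below, weighed GFP control 5 on the St8i6a plasmid side (0.244). They weighed ST8Sia6 plasmid 4 and 5 on the side of GFP cells of the interaction (-0.255 and -0.247). The lack of passing genes therefore does not show that the plasmid changed nothing. Among the genes with the lowest unadjusted p-values, none of which passed, PCK2, a mitochondrial enzyme of gluconeogenesis, had 44.3 ± 5.69 CPM under the ST8Sia6 plasmid label and 30.1 ± 3.09 CPM under the GFP control label (SD, n = 5 and 5). STC2, a secreted glycoprotein, had 23.5 ± 10.6 against 8.38 ± 2.31 CPM, and CSKMT had 13.4 ± 2.82 against 7.15 ± 1.92 CPM. Lower values were measured for SPOCK2, a proteoglycan of the extracellular matrix, at 3.12 ± 0.702 against 14.3 ± 9.14 CPM, and for TSPAN15, a tetraspanin, at 13.4 ± 3.70 against 26.1 ± 4.29 CPM. TBXA2R, the thromboxane receptor, had 8.18 ± 1.37 against 13.2 ± 1.41 CPM. The log2 fold changes were 0.58 (PCK2), 0.92 (CSKMT), -2.17 (SPOCK2), -0.94 (TSPAN15) and -0.66 (TBXA2R), with standard errors between 0.12 and 0.44. In build susScr11, PCK2 (ENSSSCG00000002009.4) lies on chromosome 7 from 75187194 to 75197733 and SPOCK2 (ENSSSCG00000010283.4) on chromosome 14 from 74938179 to 74968388.

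Of 13840 genes tested, 0 passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of each named gene being 0.502. At an unadjusted p under 0.05 there were 1367 genes, and DESeq2 called 12 genes (2 higher, 10 lower, PCK2, STC2, SPOCK2, TSPAN15 and TBXA2R among them) and limma-voom called 0. Leaving out the library labelled ST8Sia6 plasmid 1 gave 1 gene.

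Although no single gene passed, 14 of 26 gene lists fixed before the data were examined differed from the other genes with the correlation between members preset at 0.01 (camera), 5 upward and 9 downward, and 0 did so with an estimated correlation. Of 35 cell cycle genes, 34 had a positive log2 fold change, with a median of 0.49 (camera adjusted p = 4.54e-11; adjusted p = 0.456 with an estimated correlation). The list's mean log2(CPM + 0.5) was 4.93 and 5.02 in GFP control 3 and 4, and in GFP control 1, 2 and 5 (5.97, 5.93 and 6.25) it lay within the 5.91 to 6.29 of ST8Sia6 plasmid. BUB1, a spindle checkpoint kinase, was at 62.9 ± 3.55 against 43.9 ± 12.6 CPM and E2F1, a transcription factor of S phase entry, at 22.0 ± 3.54 against 14.9 ± 4.40 CPM. The 7 MHC class II genes had a median of -0.95 (adjusted p = 1.19e-05; 0.351 with an estimated correlation), and 5 were lower when adjusted over the list alone. CD74, the invariant chain, had 581 ± 212 against 1133 ± 243 CPM, SLA-DQB1 had 49.0 ± 34.8 against 140 ± 45.6 CPM and SLA-DMB had 17.4 ± 14.2 against 41.6 ± 6.94 CPM. The list mean of ST8Sia6 plasmid 1 (5.93) lay within GFP control (5.81 to 6.07), and the other 4 libraries were at 4.19 to 4.97. The SLA genes have near-identical copies, so their counts are uncertain where reads were shared. The 24 NF-kB cytokine and chemokine genes had a median of 0.69, with 21 positive (adjusted p = 5.39e-05; 0.456 with an estimated correlation). Over 27 listed genes with counts, mean log2(CPM + 0.5) was 5.90 and 5.58 in ST8Sia6 plasmid 4 and 5, above 10% mitochondrial. It was 4.89, 5.14 and 4.16 in ST8Sia6 plasmid 1, 2 and 3, against 4.37 to 5.04 in GFP control. In that group IRAK3, an inhibitor of Toll-like receptor signalling, had 110 ± 26.2 against 69.7 ± 18.4 CPM, IL1A had 79.8 ± 51.3 against 22.7 ± 18.1 CPM and CXCL8, a neutrophil chemokine, had 134 ± 156 against 21.8 ± 20.7 CPM.

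The 13 mitochondrially encoded genes had a median log2 fold change of 2.44 (camera adjusted p = 4.03e-05; adjusted p = 0.456 with an estimated correlation), with 12 higher when adjusted over the list alone. COX3 was at 7006 ± 7872 against 976 ± 367 CPM and ND3 at 301 ± 344 against 36.9 ± 14.1 CPM, and ST8Sia6 plasmid 4 and 5 were the libraries of this comparison above 10% mitochondrial. With only the libraries under 10% mitochondrial, the median of this list was -0.08. Of the mesenchymal and extracellular matrix list, 6 of 29 genes were positive (median -0.26, adjusted p = 5.39e-05; 0.456 with an estimated correlation), SPARC being at 1646 ± 781 against 3595 ± 1455 CPM and COL4A1 at 1560 ± 503 against 2494 ± 876 CPM. Its mean log2(CPM + 0.5) was below GFP control (7.75 to 8.52) in ST8Sia6 plasmid 4 and 5 (7.48 and 7.65) and within it in ST8Sia6 plasmid 1 to 3 (7.80 to 8.08). Of 22 lysosome and autophagy genes, 4 were positive (median -0.35, adjusted p = 9.58e-05; 0.456 with an estimated correlation), CTSB being at 516 ± 205 against 837 ± 207 CPM and LAMP2 at 247 ± 75.4 against 358 ± 71.8 CPM. In mean log2(CPM + 0.5) the lysosome list was at 5.70 and 5.65 in ST8Sia6 plasmid 4 and 5, above 10% mitochondrial, while ST8Sia6 plasmid 1 to 3 (6.26 to 6.35) lay within GFP control (6.14 to 6.60). The 17 p53 and apoptosis genes had a median of -0.21 (adjusted p = 0.000199; 0.351 with an estimated correlation), and 4 were lower when adjusted over the list alone. CDKN1A, a cell cycle inhibitor, had 338 ± 66.4 against 536 ± 100 CPM, FAS, a death receptor, had 21.3 ± 3.60 against 31.1 ± 4.62 CPM, and BCL2L1, which opposes apoptosis, had 169 ± 37.5 against 247 ± 31.1 CPM. The p53 list mean of ST8Sia6 plasmid 1 (5.90) lay within GFP control (5.87 to 6.09), and the other 4 libraries were at 5.61 to 5.70.

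The remaining calls with the preset correlation were downward for kidney epithelial markers (adjusted p = 0.00511), coagulation and thromboregulation (0.00671), complement and its regulators (0.00776), immediate early genes (0.0191) and the sialic acid pathway (0.0338), each with adjusted p = 0.456 with an estimated correlation. They were upward for hypoxia and glycolysis (0.0372; 0.747 with an estimated correlation) and for oxidative stress and metallothionein (0.0425; 0.52 with an estimated correlation). Complement genes averaged 3.43 and 3.33 in mean log2(CPM + 0.5) in ST8Sia6 plasmid 4 and 5, against 4.57 to 4.83 in ST8Sia6 plasmid 1 to 3 and 4.41 to 5.13 in GFP control, and coagulation genes 4.66 and 4.65, against 5.17 to 5.28 and 5.06 to 5.64. Kidney epithelial markers were at 3.32, 3.43 and 3.83 in ST8Sia6 plasmid 4, 5 and 2, below GFP control (4.15 to 4.85), with ST8Sia6 plasmid 1 and 3 (4.35 and 4.54) within it. The sialic acid list was below GFP control (3.39 to 3.80) in ST8Sia6 plasmid 4 and 5 (3.18 and 3.32) alone. Immediate early genes were lowest in ST8Sia6 plasmid 2 and 3 (4.91 in both, GFP control 5.14 to 5.61), with ST8Sia6 plasmid 4 and 5 (5.50 and 5.36) within GFP control. Hypoxia genes were above GFP control (6.09 to 6.71) in ST8Sia6 plasmid 2 (6.89) alone, and oxidative stress genes (GFP control 5.83 to 6.23) in ST8Sia6 plasmid 2, 3 and 4 (6.55, 6.28 and 6.25). No member of these lists passed over all genes, and 1 oxidative stress gene was higher when adjusted over the list alone. In the sialic acid pathway, where 5 of 18 genes were positive (median -0.29), NEU3, a sialidase of the plasma membrane, had 7.96 against 10.9 CPM (log2 fold change -0.43 ± 0.14, SE) and ST3GAL5, the ganglioside GM3 synthase, had 6.87 ± 4.54 against 18.7 ± 12.8 CPM. These sialic acid genes and ST8SIA5 were named in addition to the fixed rule after their values were seen, because their list holds the gene of the plasmid.

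Cells labelled cell-cell interaction differed widely from those labelled GFP control. By its labels this comparison asks what contact with PBMCs changes. The authors' deposited fold changes, described below, weighed cell-cell interaction 1 and 2 on the side of GFP cells of the interaction (-0.251 and -0.250). Cell-cell interaction 3, 4 and 5 weighed on the side of St8i6a cells of the interaction (-0.248, -0.293 and -0.330). GFP control 5 weighed on the St8i6a plasmid side (0.244). By these weights the comparison mixed plasmid with contact. GDF6, a growth factor of the BMP family, rose from 2.08 ± 0.718 CPM to 60.1 ± 27.2 CPM (SD, n = 5 and 5), a log2 fold change of 4.88 ± 0.38 (SE). ALDH1A3, an enzyme of retinoic acid synthesis, rose from 0.361 ± 0.145 to 10.4 ± 4.18 CPM, and NID1, a basement membrane protein, rose from 0.964 ± 0.206 to 21.8 ± 12.7 CPM. CLDN8, a tight junction claudin, fell from 45.2 ± 11.3 to 2.07 ± 1.04 CPM, with a log2 fold change of -4.39 ± 0.34. EPCAM, an epithelial adhesion molecule, fell from 10.1 ± 7.63 to 0.588 ± 0.201 CPM, and CYP24A1, which degrades vitamin D hormone, fell from 38.3 ± 36.0 to 0.401 ± 0.186 CPM.

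The other large rises by the fixed rule were in SLITRK2 (log2 fold change 5.86), CHST4 (5.16) and the mitochondrial gene ATP8 (4.55), and the other large falls were in TRPV6 (-5.48), CLSTN3 (-4.65) and GPM6A (-3.98). In build susScr11, GDF6 (ENSSSCG00000034943.1) lies on chromosome 4 from 40473013 to 40489032, NID1 (ENSSSCG00000026819.3) on chromosome 14 from 55239652 to 55435207 and CLDN8 (ENSSSCG00000012030.3) on chromosome 13 from 193562074 to 193564168. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5510 of 13951 genes passed, 2899 higher and 2611 lower, 1305 of them without a symbol. The adjusted p was 4.54e-05 for GDF6, ALDH1A3 and CLDN8, 0.00015 for NID1, 0.00058 for EPCAM and 0.000424 for CYP24A1. The libraries of both labels did not overlap for 3429 genes, 24.6% of those tested against the 0.794% that chance gives.

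Of the 13 mitochondrially encoded genes all 13 rose (median 3.70, camera adjusted p = 8.13e-09; adjusted p = 0.562 with an estimated correlation), COX3 by a log2 fold change of 3.92 ± 0.52 (SE). They also rose when adjusted over the list alone, and 4 of the 5 cell-cell interaction libraries were above 10% mitochondrial. Counts of list members here stand beside 5510 of 13951 genes passing over all, 2899 higher and 2611 lower. Of 25 NF-kB cytokine and chemokine genes, 15 rose, 0 fell and 10 did not pass, and 16 rose when adjusted over the list alone (median 1.20, adjusted p = 1.19e-05; 0.562 with an estimated correlation). The list's mean log2(CPM + 0.5) in cell-cell interaction 4 (4.84) lay within GFP control (4.37 to 5.04). Cell-cell interaction 1, 2, 3 and 5 were at 5.35 to 6.21. ZC3H12A, an RNase that degrades cytokine messages, rose from 58.1 ± 10.1 to 168 ± 34.3 CPM, CSF1, a macrophage growth factor, from 132 ± 20.4 to 300 ± 74.9 CPM and RELB, an NF-kB subunit, from 29.1 ± 3.17 to 47.9 ± 7.83 CPM. Of 7 MHC class II genes 5 fell, as they did when adjusted over the list alone (median -2.34, adjusted p = 0.000667; 0.501 with an estimated correlation). SLA-DMB fell from 41.6 ± 6.94 to 6.32 ± 2.12 CPM and CD74 from 1133 ± 243 to 375 ± 56.4 CPM.

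Of 24 cholesterol synthesis genes 11 fell, 0 rose and 13 did not pass, and 12 were lower when adjusted over the list alone (median -0.51, camera adjusted p = 0.00104; adjusted p = 0.678 with an estimated correlation). SCD, a fatty acid desaturase kept in that list, fell from 368 to 75.7 CPM (log2 fold change -2.25 ± 0.37, SE). Of 22 lysosome and autophagy genes 13 fell and 1 rose, as they did when adjusted over the list alone (adjusted p = 0.00104; 0.632 with an estimated correlation). GPNMB fell by 1.88 and NPC2, a cholesterol carrier of the lysosome, by 0.67 on the log2 scale. Complement genes fell in 5 of 9 cases, also when adjusted over the list alone (median -1.39, adjusted p = 0.00607; 0.562 with an estimated correlation), SERPING1, the C1 inhibitor, from 162 ± 53.9 to 18.5 ± 10.3 CPM and CFB from 10.1 ± 2.75 to 2.59 ± 1.11 CPM. Coagulation and thromboregulation genes fell in 5 of 15 cases, also when adjusted over the list alone (adjusted p = 0.00423; 0.57 with an estimated correlation), PLAT, the tissue plasminogen activator, from 466 ± 116 to 132 ± 98.9 CPM and PTGIS, the prostacyclin synthase, from 2.22 ± 0.836 to 0.105 ± 0.115 CPM.

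Kidney epithelial markers fell in 8 of 13 cases and rose in 2, also when adjusted over the list alone (camera adjusted p = 0.029; adjusted p = 0.562 with an estimated correlation). CDH1, the E-cadherin of epithelial junctions, fell from 366 ± 127 to 55.6 ± 24.9 CPM, and PAX2, a transcription factor of kidney development, rose from 112 ± 9.63 to 165 ± 23.6 CPM. Of 17 p53 and apoptosis genes 7 fell and 0 rose, also when adjusted over the list alone (adjusted p = 0.029; 0.562 with an estimated correlation). Both CDKN1A, from 536 ± 100 to 217 ± 39.1 CPM, and BCL2L1, which opposes apoptosis, from 247 ± 31.1 to 130 ± 10.1 CPM, were among them. In the sialic acid pathway 6 of 19 genes fell and 2 rose, without a call for the list (adjusted p = 0.354), ST3GAL5 falling from 18.7 ± 12.8 to 2.16 ± 1.13 CPM and ST8SIA5, another sialyltransferase, from 10.4 ± 5.61 to 3.03 ± 1.52 CPM.

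**Figure D2:**
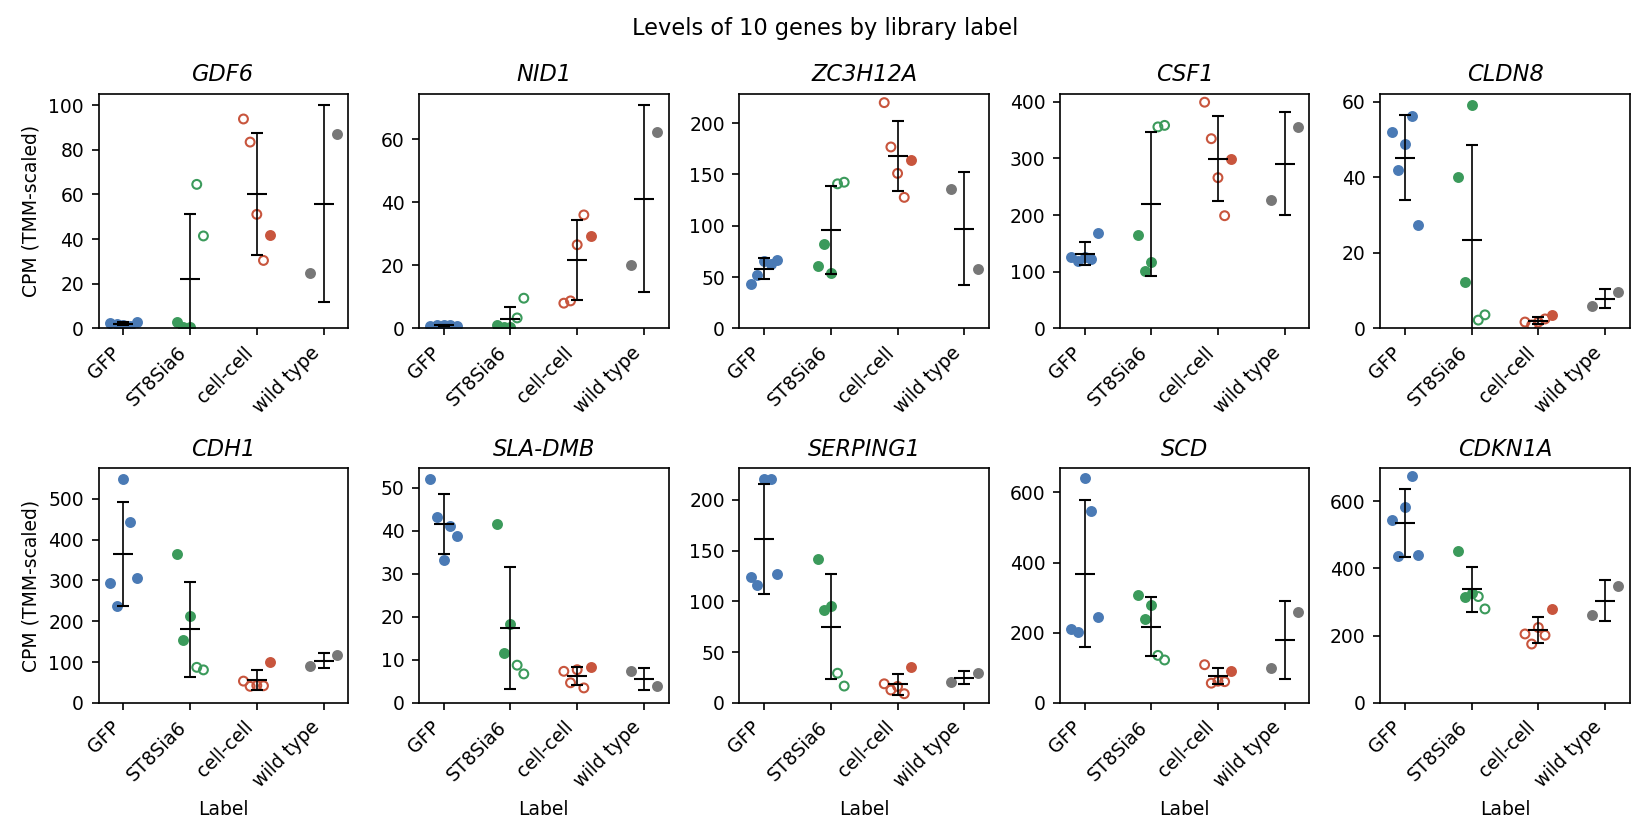
TMM-scaled CPM of 10 named genes in each library labelled GFP control, ST8Sia6 plasmid, cell-cell interaction (n = 5 each) and wild type (n = 2), where points are libraries, open circles are libraries above 10% mitochondrial and black bars are mean ± SD. GDF6 averaged 2.08 CPM under the GFP control label and 60.1 CPM under the cell-cell interaction label, and CLDN8 averaged 45.2 and 2.07 CPM.

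**Figure D3:**
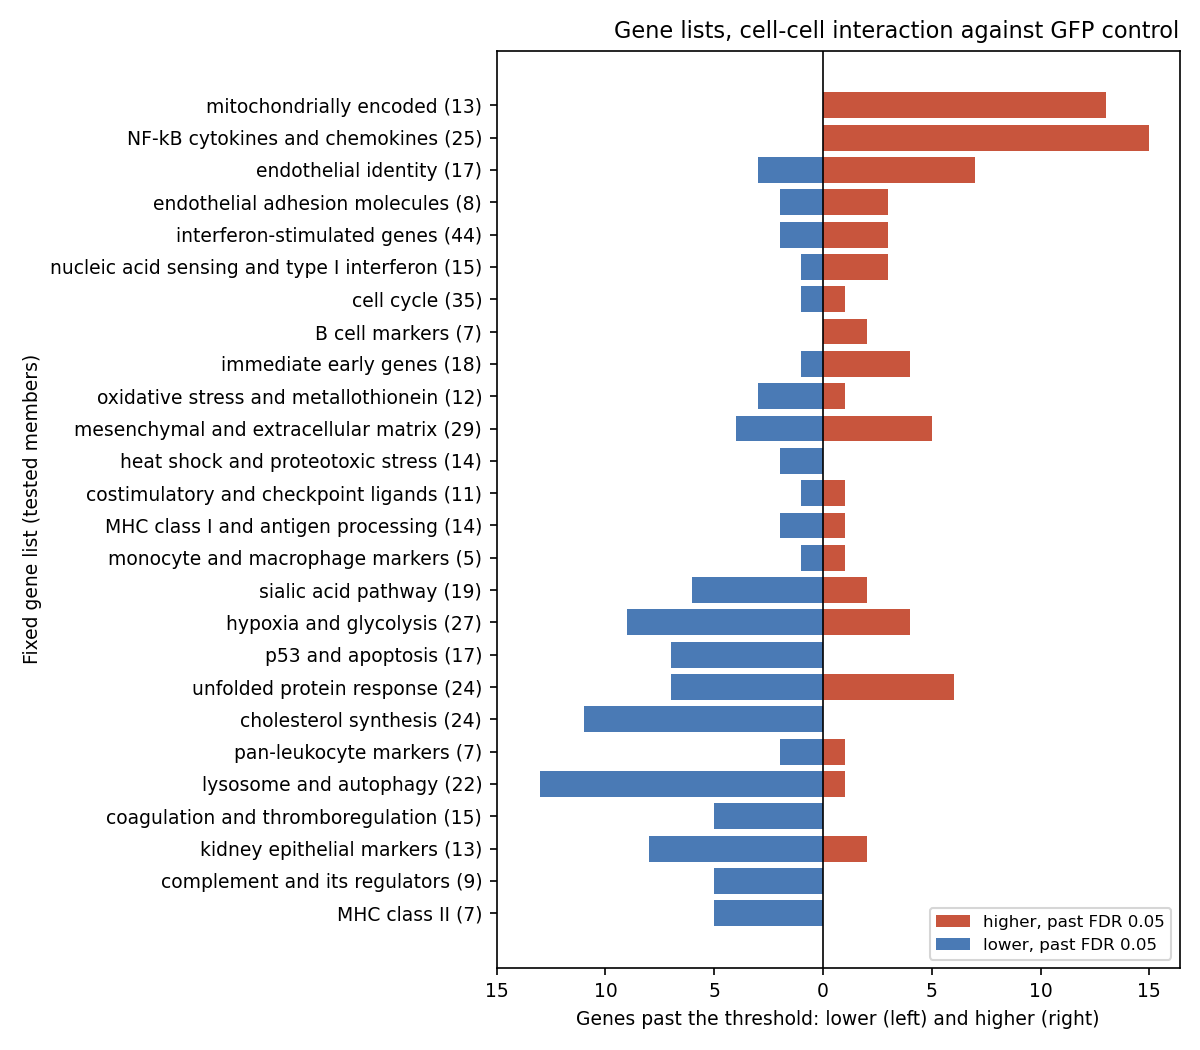
Number of members of each fixed gene list that were lower (left) or higher (right) past a false discovery rate of 0.05 between cell-cell interaction and GFP control, with the number of tested members in parentheses. NF-kB cytokines and chemokines had 15 members higher and 0 lower, and cholesterol synthesis had 11 lower and 0 higher. Over all 13951 genes tested, 2899 were higher and 2611 lower.

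The count of the cell-cell interaction comparison depended on which libraries were compared. With only libraries under 10% mitochondrial, which left cell-cell interaction 5 alone against 5 GFP control libraries, 140 genes passed, 108 of them shared with the 5510, and 25 of the 32 genes taken by the naming rule no longer passed, the others being GDF6, ALDH1A3, NID1, CLDN8, GPM6A, ZC3H12A and SLA-DMB. In that fit 4 NF-kB genes were higher, 2 MHC class II genes were lower, and 0 mitochondrially encoded, cholesterol synthesis, lysosome, complement, coagulation, kidney epithelial or p53 genes passed. The list levels of cell-cell interaction 5 differed in this from list to list. In mean log2(CPM + 0.5), cholesterol synthesis was at 5.02 in it, below the other 4 libraries of its label (5.32 to 5.97) and GFP control (5.74 to 6.28), and kidney epithelial markers were at 3.38, below GFP control (4.15 to 4.85). Lysosome genes at 6.42 and coagulation genes at 5.33 lay within GFP control (6.14 to 6.60 and 5.06 to 5.64), where the other 4 libraries had 5.43 to 5.69 and 4.39 to 4.52. Complement (4.31) and p53 genes (5.77) lay just below GFP control (lowest 4.41 and 5.87), and mitochondrially encoded genes (9.16) above it (highest 8.61) and below the other 4 libraries (11.29 to 12.40). With mutually closest libraries of 1 label summed into 1, 2461 genes passed (1247 higher, 1214 lower), 2335 of them shared with the 5510, and GPNMB and PAX2 no longer passed. In that fit 11 NF-kB genes were higher, and 5 MHC class II, 7 cholesterol synthesis, 2 lysosome, 4 complement, 2 coagulation, 4 kidney epithelial and 5 p53 genes were lower. PAX2 also did not pass without GFP control 1 and 2, the libraries with leukocyte transcripts, where 9 NF-kB genes were higher and 8 lysosome genes lower.

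The libraries labelled cell-cell interaction were also set against those labelled ST8Sia6 plasmid. The authors' deposited fold changes, described below, weighed ST8Sia6 plasmid 4 and 5 on the side of GFP cells of the interaction (-0.255 and -0.247). The ST8Sia6 plasmid label may thus hold co-cultured cells too, so rises and falls here are directions between labels. The transcription factor RUNX1 rose from 37.8 ± 5.14 CPM under the ST8Sia6 plasmid label to 76.3 ± 10.5 CPM under the cell-cell interaction label (SD, n = 5 and 5). Its log2 fold change was 1.05 ± 0.13 (SE). TRIM9, a ubiquitin ligase, rose from 1.76 ± 0.224 to 5.11 ± 1.49 CPM and HIC1, a transcriptional repressor, from 5.23 ± 1.07 to 11.5 ± 1.84 CPM. EGLN3, a prolyl hydroxylase of the hypoxia response, fell from 11.3 ± 2.18 to 4.87 ± 0.836 CPM, WNT7B, a secreted Wnt ligand, from 16.4 ± 2.45 to 7.84 ± 1.59 CPM and TYMS, the thymidylate synthase of DNA synthesis, from 87.8 ± 9.61 to 53.8 ± 4.62 CPM. INAVA (0.85), KIAA0930 (0.80) and TCF4 (0.80) rose by the log2 fold changes given. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 22 of 13849 genes passed, 18 higher and 4 lower, 4 of them without a symbol. RUNX1 (ENSSSCG00000035537.2) lies on chromosome 13 from 198371835 to 198638189 and TYMS (ENSSSCG00000040678.2) on chromosome 6 from 105640031 to 105660601. The adjusted p was 0.0198 for RUNX1, 0.0456 for TCF4 and 0.0414 for the other 7 named genes. The libraries of both labels did not overlap for 1198 genes, 8.65% of those tested against 0.794% by chance.

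In this comparison 6 of 26 gene lists were called by camera with the preset correlation, each at adjusted p = 0.689 with an estimated correlation. Of 35 cell cycle genes, 1 fell (TYMS), 34 did not pass and 9 were lower when adjusted over the list alone (median -0.33, adjusted p = 9.98e-06), TOP2A being at 152 ± 18.4 against 249 ± 26.1 CPM and MCM6 at 86.6 ± 7.60 against 123 ± 13.0 CPM. The list's mean log2(CPM + 0.5) was 5.21 in cell-cell interaction 5 and 5.85 in cell-cell interaction 4, and in cell-cell interaction 1 to 3 (5.92 to 6.01) it lay within ST8Sia6 plasmid (5.91 to 6.29). Of 24 cholesterol synthesis genes, 0 passed and 9 were lower when adjusted over the list alone (median -0.51, adjusted p = 5.85e-05), SCD being at 75.7 against 217 CPM (log2 fold change -1.48 ± 0.30, SE). The list mean of cell-cell interaction 1 (5.97) lay within ST8Sia6 plasmid (5.81 to 6.34), and the other 4 libraries were at 5.02 to 5.56. Of 27 hypoxia and glycolysis genes, 1 fell (EGLN3), and 2 were higher and 8 lower when adjusted over the list alone (adjusted p = 0.00581). The list mean was 6.89 and 6.70 in ST8Sia6 plasmid 2 and 3, while ST8Sia6 plasmid 4 and 5 (6.23 and 6.16) lay within cell-cell interaction (5.88 to 6.36). The 26 NF-kB genes had a median of 0.55, which was -0.07 with only libraries over 10% mitochondrial, with 0 passing and 2 higher when adjusted over the list alone (adjusted p = 0.00581), RELB being at 47.9 ± 7.83 against 29.9 ± 4.83 CPM. The NF-kB list mean of cell-cell interaction 3 and 4 (5.35 and 4.84) lay within ST8Sia6 plasmid (4.16 to 5.90). The 13 mitochondrially encoded genes had 0 passing on either basis (adjusted p = 0.00581), ND2 being at 3528 ± 1934 against 1340 ± 1494 CPM, and 4 libraries of the first label against 2 of the second were above 10% mitochondrial. Of 14 heat shock genes 0 passed and 6 were lower when adjusted over the list alone (median -0.27, adjusted p = 0.0112), HSPA4 being at 188 ± 5.41 against 247 ± 20.8 CPM. The heat shock list mean of cell-cell interaction 1 (6.90) lay within ST8Sia6 plasmid (6.82 to 7.13), and the other 4 libraries were at 6.51 to 6.78.

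The 22 genes depended on single libraries and on the method. Without ST8Sia6 plasmid 1, 2, 3, 4 and 5 the count was 1, 0, 0, 3 and 2806, and without cell-cell interaction 1, 2, 3, 4 and 5 it was 4, 0, 0, 0 and 3308. The count was 2784 by DESeq2, 337 by limma-voom, 352 in libraries over 10% mitochondrial, 2 in libraries under 10% and 0 with mutually closest libraries summed.

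Cells labelled wild type were set against GFP control for a baseline without a plasmid named in the label. Wild type 1 may not be such a baseline. The authors' deposited fold changes, described below, weighed it on the St8i6a side of the interaction (-0.219), and its closest library was cell-cell interaction 5. HLA-DRA, as the gene table names this MHC class II gene, fell from 311 ± 38.1 to 7.80 ± 5.32 CPM (SD, n = 5 and 2; log2 fold change -5.32 ± 0.46, SE). SIGLEC1, a sialic acid-binding receptor of macrophages that is induced by interferon, fell from 10.6 ± 5.75 to 0.0833 ± 0.0644 CPM and TRPV6, a calcium channel, from 5.80 ± 4.65 to 0.102 ± 0.0377 CPM. Rises were found for SLITRK2, a neuronal membrane protein, from 0.0899 ± 0.0926 to 9.52 ± 10.3 CPM, and for CCL11, an eosinophil chemokine, from 0.144 ± 0.117 to 8.69 ± 9.33 CPM. SHISA9 had no count in any GFP control library and 1.51 and 10.8 CPM in wild type 1 and 2. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 458 of 14496 genes passed, 285 higher and 173 lower, 65 of them without a symbol. The adjusted p was 0.00279 for HLA-DRA, 0.0117 for SIGLEC1, 0.0425 for TRPV6, 0.0143 for SLITRK2, 0.0126 for CCL11 and 0.0477 for SHISA9. HLA-DRA (ENSSSCG00000001453.5) lies on chromosome 7 from 24825053 to 24835160 and SIGLEC1 (ENSSSCG00000007146.5) on chromosome 17 from 31994540 to 32021466. The libraries of both labels did not overlap for 3712 genes, 25.6% of those tested against 9.52% by chance.

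Of 44 interferon-stimulated genes, 2 fell in wild type, 42 did not pass and the same count of 2 was lower when adjusted over the list alone (median -1.95, camera adjusted p = 1.24e-12; adjusted p = 0.478 with an estimated correlation). In mean log2(CPM + 0.5) the list was at 2.71 in wild type 2, while wild type 1 (5.54) lay within GFP control (5.38 to 7.61). The genes that fell were CXCL9, from 4.90 to 0.0644 CPM (log2 fold change -6.09 ± 0.75, SE), and ISG20, from 19.1 ± 5.92 to 3.04 ± 2.27 CPM. Of 7 MHC class II genes, 5 fell and 7 were lower when adjusted over the list alone (median -2.52, adjusted p = 4.95e-09; 0.385 with an estimated correlation), SLA-DMB from 41.6 ± 6.94 to 5.63 ± 2.52 CPM and SLA-DMA from 56.0 ± 5.92 to 9.79 ± 5.15 CPM. Complement genes fell in 4 of 9 cases, with 1 higher and 5 lower when adjusted over the list alone (adjusted p = 0.00233; 0.478 with an estimated correlation), C2 from 5.57 ± 0.746 to 0.454 ± 0.269 CPM and SERPING1 from 162 ± 53.9 to 24.8 ± 6.45 CPM. Of 29 mesenchymal genes, 5 rose and 8 were higher when adjusted over the list alone (median 0.56, adjusted p = 3.41e-05; 0.478 with an estimated correlation), COL3A1, a fibrillar collagen, from 167 ± 35.2 to 1045 ± 611 CPM and PDGFRB, a receptor of pericytes and fibroblasts, from 2.40 ± 1.29 to 67.2 ± 58.5 CPM. NF-kB genes rose in 3 of 27 cases, with 10 higher and 1 lower when adjusted over the list alone (adjusted p = 3.41e-05; 0.478 with an estimated correlation), CSF1 from 132 ± 20.4 to 291 ± 91.5 CPM and IL33 from 0.226 ± 0.130 to 2.82 ± 2.53 CPM. The NF-kB list mean was above GFP control (4.37 to 5.04) in wild type 1 (5.67) and within it in wild type 2 (4.63). Of 13 mitochondrially encoded genes, 2 rose, and 11 were higher and 1 lower when adjusted over the list alone (adjusted p = 8.72e-06; 0.478 with an estimated correlation), ND3 from 36.9 ± 14.1 to 141 ± 57.0 CPM. That list mean was above GFP control (7.53 to 8.61) in wild type 2 (9.89) and within it in wild type 1 (8.59).

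Camera with the preset correlation also called lists in which no or few single genes passed, each lost with an estimated correlation. These were downward for cholesterol synthesis (0 of 24 passing, adjusted p = 1.17e-06; 0.478 with an estimated correlation), cell cycle (0 of 35, 3.66e-06; 0.584), MHC class I and antigen processing (0 of 14, 2.63e-05; 0.478), NK and cytotoxic cell markers (1 of 6, 0.014; 0.478), heat shock (0 of 14, 0.0215; 0.504) and lysosome and autophagy (0 of 22, 0.0231; 0.478). They were upward for hypoxia and glycolysis (1 of 27, 0.0169; 0.653). For 5 of these lists a single wild type library lay outside the range of GFP control in mean log2(CPM + 0.5). It was wild type 1 for cholesterol synthesis (5.10, wild type 2 at 5.81, GFP control 5.74 to 6.28). It was wild type 2 for cell cycle (4.42, wild type 1 at 5.32, GFP control 4.93 to 6.25), MHC class I (5.50, 6.99, 6.97 to 7.66), lysosome (6.08, 6.21, 6.14 to 6.60) and hypoxia (6.91, 6.38, 6.09 to 6.71). NK cell markers were at 2.78 and 3.30 in GFP control 1 and 2, the libraries with leukocyte transcripts, against 1.54 to 1.74 in GFP control 3 to 5 and 1.02 and 0.12 in wild type 1 and 2. The wild type comparison rested on few libraries. Without wild type 2 the count was 65, without GFP control 1, 2, 4 and 5 it was 160, 187, 190 and 278, without both GFP control 1 and 2 it was 27, and with mutually closest libraries summed it was 7. Of the 17 genes named here, 16 did not pass without GFP control 1 and 2 (HLA-DRA did), and 0 passed with the libraries summed.

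The library labelled KEC plus all cells had no replicate and entered no test. Its mean log2(CPM + 0.5) over 44 interferon-stimulated genes was 2.73, against 5.38 to 7.61 in GFP control and 2.71 to 5.54 in wild type. MHC class II genes averaged 3.34 in it, against 5.81 to 6.07 in GFP control and 3.30 to 4.10 in wild type. Cell cycle genes averaged 4.38 in it, against 4.93 to 6.25 in GFP control and 4.42 to 5.32 in wild type. Its summed pan-leukocyte markers were 27.4 CPM, against 25.2 and 42.8 CPM in wild type 2 and 1.

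The authors' deposited tables held 4 comparisons, which were read as deposited. At a false discovery rate under 0.05 the authors' deposited table called 209 genes between St8i6a plasmid and GFP control (64 higher, 145 lower) and 7549 genes between GFP control and GFP cells of the cell-cell interaction. It called 3839 genes between St8i6a plasmid and St8i6a cells of the cell-cell interaction, and 723 genes between the GFP and St8i6a cells of the interaction. For ST8SIA6 the authors' deposited table gave a log2 fold change of 0.96 in the St8i6a plasmid minus GFP control comparison, with a false discovery rate of 0.874, and of 4.42 in the comparison of GFP minus St8i6a cells of the interaction, with a false discovery rate of 0.271. The change was -4.70 for GFP control minus GFP cells of the interaction (false discovery rate 0.0863). For St8i6a plasmid minus St8i6a cells of the interaction it was 0.67 (false discovery rate 0.833). The groups behind these columns were not those of the sample labels. When the authors' deposited log2 fold changes of 10466 genes were regressed on the log2 CPM of the 18 libraries (R² between 0.974 and 0.996), the library labelled GFP control 5 had a weight of 0.244 on the St8i6a plasmid side, and the libraries labelled ST8Sia6 plasmid 4 and 5 had weights of -0.0157 and 0.00461. In the comparison of GFP control minus GFP cells of the interaction, ST8Sia6 plasmid 4 and 5 had weights of -0.255 and -0.247, beside -0.251 and -0.250 for cell-cell interaction 1 and 2. Wild type 1 had a weight of -0.219 on the St8i6a side of the last comparison, beside -0.248, -0.293 and -0.330 for cell-cell interaction 3, 4 and 5. Labels rather than these weights set the groups of every test in this report.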

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

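The counts over other splits of the libraries were planned before their results were seen, and the other tests of explanations here were chosen after the result was seen.

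Among 159 groups of libraries examined, 8 held a library far from the others of its label. Chance would give about 1 in 20 if the groups were independent. They are genes and measures of the same libraries, so this rate decides nothing about chance. All 8 flags fell on GFP control 5 and cell-cell interaction 5. Log2 CPM in the library labelled GFP control 5 was 6.68 for IRAK3 (others 5.83 to 6.03), 5.88 for CXCL8 (others 3.34 to 4.07), 7.40 for CSF1 (others 6.89 to 6.98) and 4.91 for ISG20 (others 4.01 to 4.13). In cell-cell interaction 5 it was 8.27 for PLAT (others 6.24 to 6.75), 6.97 for PAX2 (others 7.39 to 7.55) and 3.47 for WNT7B (others 2.89 to 3.05). The summed CPM of pan-leukocyte markers in cell-cell interaction 5 was 57.6, against 28.9 to 36.7 in the other 4 libraries of that label.

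The library labelled KEC plus all cells, which entered no comparison, had 7 lists whose mean log2(CPM + 0.5) lay above every GFP control library and 12 below every GFP control library. Such levels were not particular to it. Wild type 2, its closest library, was at 2.71 against 2.73 for interferon-stimulated genes, 3.30 against 3.34 for MHC class II and 9.89 against 9.93 for mitochondrially encoded genes. The means above were 4.88 for endothelial adhesion molecules (highest GFP control 4.59), 2.19 for endothelial identity (1.69), 8.89 for mesenchymal and extracellular matrix genes (8.52), 6.91 for hypoxia and glycolysis (6.71), 6.40 for oxidative stress and metallothionein (6.23), 9.93 for mitochondrially encoded genes (8.61) and 1.11 for B cell markers (0.78). The lists below were interferon-stimulated genes (2.73, lowest GFP control 5.38), nucleic acid sensing (4.13, 4.24), MHC class I (5.53, 6.97), MHC class II (3.34, 5.81), complement (3.93, 4.41), costimulatory ligands (4.05, 4.33), cell cycle (4.38, 4.93), heat shock (6.62, 6.70), p53 (5.81, 5.87), lysosome (6.11, 6.14), NK cell markers (0.18, 1.54) and monocyte markers (0.24, 0.49).

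ST8SIA6 counts did not separate the labels. Transcripts of the plasmid that the pig gene's counts cannot see may account for this, since the labels do not give the species or extent of the plasmid's coding sequence, but 2 of the 5 libraries labelled ST8Sia6 plasmid had more ST8SIA6 counts than any labelled GFP control, which decides nothing. Of those 2 libraries, ST8Sia6 plasmid 5 had a weight of -0.247 on the side of GFP cells of the interaction. Sample labels that differ from the groups behind the authors' comparison are another candidate explanation, as GFP control 5 carried a weight of 0.244 on the St8i6a side of it. ST8SIA6 did not separate those groups either, with a false discovery rate of 0.874 in the authors' deposited table, so this also stays open. A biological effect of the plasmid on the pig gene was not tested.

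The high mitochondrial share of 6 libraries moved with the cell-cell interaction label but not fully, since 3 libraries lay on the other side of 10% than that label alone would give. The label is therefore not the whole account, although ST8Sia6 plasmid 4 and 5 had weights of -0.255 and -0.247 on the co-culture side of the authors' deposited table, so that all 6 libraries lay in its co-culture arms, with cell-cell interaction 5 (3.32%) and wild type 1 (2.29%). A shift of the scaling by a few genes that take many counts is argued against as the cause of the gene count, because 5517 genes passed with mitochondrial genes left out against 5510 with them. RNA quality, handling and a response of the cells in co-culture remain open and untested, and the shallower depth of the same 6 libraries cannot be separated from their mitochondrial share.

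Wild type 2 and KEC plus all cells 1 were nearly alike. Deposit of 1 library under 2 labels is argued against by a chi-square of 2.31 per degree of freedom, which is above sampling noise, although the next closest of the 153 pairs was at 5.45. This chi-square covers counting error only, so it does not tell whether the libraries came from the same cells. Transcripts of other cell types in the KEC plus all cells library could not be decided, as its summed pan-leukocyte markers were 27.4 CPM, between wild type 2 (25.2) and wild type 1 (42.8). The species of the PBMCs is not given in the sources used here, and reads from another species' cells may not be counted on pig genes. No biological explanation was tested.

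For each comparison of 5 against 5 libraries, 100 splits of the 10 libraries into groups of that size were drawn out of 126, the labelled one included. Between ST8Sia6 plasmid and GFP control, the labels gave 0 genes, so that all 100 splits gave at least as many whatever the data, and the count decides nothing about chance. The highest other split gave 1523 genes. Between cell-cell interaction and GFP control, 1 split of 100 gave as many as 5510 genes, the labelled one, and the highest other gave 4000 genes. This does not exclude chance, because it would do so only if the libraries were independent. GFP control 1 and 2, GFP control 3 and 4, and cell-cell interaction 3 and 4 were each other's closest libraries. The labels keep such pairs together, while other splits can part them. With these pairs summed, 2461 genes passed. The labels do not say which libraries share an experiment. Between cell-cell interaction and ST8Sia6 plasmid, 3 splits gave at least 22 genes, under 5 in 100, but the highest other gave 4912 genes, with ST8Sia6 plasmid 5 among the cell-cell interaction libraries in place of cell-cell interaction 5. Splits with so many more genes than the labels point to a structure of the samples that the labels do not follow.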

How the results depend on the processing

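Fits by mitochondrial share, without mitochondrial genes, without GFP control 1 and 2 and with mutually closest libraries summed were chosen after seeing the data. The other alternatives were planned, except fry. No paired analysis was possible because the labels give the groups no shared replicate numbers. No alternative turned the sign of the ST8SIA6 difference. No named gene's log2 fold change turned its sign where the gene passed in the fit reported above or in that alternative. Turns of sign in genes that passed in neither fit were not counted. The median of the mitochondrially encoded list between ST8Sia6 plasmid and GFP control turned from 2.44 to -0.08 with only libraries under 10% mitochondrial, and that of the NF-kB list between cell-cell interaction and ST8Sia6 plasmid turned from 0.55 to -0.07 with only libraries over 10%. ST8SIA6 stayed without a call under both pseudocounts and each library left out, with differences of 0.23 to 0.97 and exact permutation p of 0.238 to 0.675. For each value that changed, the cause was not tested beyond the fewer libraries or genes in a fit.

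Between ST8Sia6 plasmid and GFP control, where 0 genes passed, DESeq2 called 12, and leaving out 1 library gave 0 to 1. Of the 5510 genes between cell-cell interaction and GFP control, 2345 had an absolute log2 fold change of at least 1, and the count was 140 with only libraries under 10% mitochondrial and 2461 with closest libraries summed. Its balance of 2899 higher and 2611 lower genes turned to 1884 and 2046 at a minimum of 5 CPM, 3134 and 3265 with all groups in 1 fit, 2271 and 2469 without GFP control 1, 2555 and 2710 without GFP control 2, 2718 and 2866 without GFP control 5, 2017 and 2340 without both GFP control 1 and 2, and 3383 and 3747 without cell-cell interaction 5. The lone cell-cell interaction library of the fit under 10% was assumed to vary like the other group. The 22 genes between cell-cell interaction and ST8Sia6 plasmid became 131 at a minimum of 5 CPM, 2784 by DESeq2, 337 by limma-voom, 1430 with all groups in 1 fit, 2 and 352 with only libraries under and over 10% mitochondrial, 1026 with that class as a term, 151 without mitochondrial genes and 0 with closest libraries summed. Leaving out 1 library gave 0 (ST8Sia6 plasmid 2 or 3, cell-cell interaction 2, 3 or 4) to 3308 (cell-cell interaction 5), with 1, 3 and 2806 without ST8Sia6 plasmid 1, 4 and 5 and 4 without cell-cell interaction 1. Its 18 higher and 4 lower genes turned to 585 and 845 with all groups in 1 fit and to 1541 and 1767 without cell-cell interaction 5. The 458 genes between wild type and GFP control became 1427 by DESeq2, 27 without GFP control 1 and 2 and 7 (3 higher, 4 lower, against 285 and 173) with closest libraries summed. Leaving out 1 library gave 65 (wild type 2) to 407 (wild type 1), with 160, 187, 190 and 278 without GFP control 1, 2, 4 and 5. The lone wild type library was assumed to vary like the other group. With an estimated correlation 0 gene lists were called in each of the 4 comparisons. Fry called 0 lists between ST8Sia6 plasmid and GFP control (14 by camera), 1 between cell-cell interaction and ST8Sia6 plasmid (6), 3 between wild type and GFP control (13) and 11 between cell-cell interaction and GFP control (9). Over the genes taken by the naming rule and their alternatives, 492 of 497 values kept their call between ST8Sia6 plasmid and GFP control and 5 gained it. The shares were 604 of 632 kept and 28 lost between cell-cell interaction and GFP control, 201 of 334 kept, 41 gained and 92 lost between cell-cell interaction and ST8Sia6 plasmid, and 185 of 267 kept and 82 lost between wild type and GFP control.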

Other observations

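Further gene lists of cell-cell interaction against GFP control had members that passed in edgeR's quasi-likelihood test without a call for the list by camera (Benjamini-Hochberg adjusted p between 0.124 and 0.957). Of these lists, fry called endothelial identity (adjusted p = 0.0382) and B cell markers (adjusted p = 0.000162) upward. Over all genes of the comparison 5510 of 13951 passed, 2899 higher and 2611 lower. Counts of passing members are to be read against that share. Interferon-stimulated, cell cycle, heat shock and costimulatory genes passed less often than that. In endothelial identity 7 of 17 genes rose and 3 fell. Endothelial adhesion molecules had 3 of 8 higher and 2 lower, and mesenchymal genes 5 of 29 higher and 4 lower (4 and 2 when adjusted over the list alone), with a median of -0.12, a mean of 0.09 and a downward test. The unfolded protein response had 6 of 24 higher and 7 lower, with DDIT3, a stress-induced transcription factor, higher by a log2 fold change of 2.64 and the chaperones MANF and CALR lower. Hypoxia and glycolysis had 4 of 27 higher and 9 lower (4 and 10 over the list alone), and interferon-stimulated genes 3 of 44 higher and 2 lower (2 and 2). Nucleic acid sensing had 3 of 15 higher and 1 lower (1 and 1), MHC class I 1 of 14 higher and 2 lower, and costimulatory and checkpoint ligands 1 of 11 each way. Immediate early genes had 4 of 18 higher and 1 lower (median -0.02, mean 0.04, upward test), oxidative stress 1 of 12 higher and 3 lower (median -0.03, mean 0.04, downward test), heat shock 2 of 14 lower, and cell cycle 1 of 35 each way (0 over the list alone). Genes named in this part outside the fixed rule were chosen after their values were seen.

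Among markers of blood cells, CD79A and EBF1 rose in the B cell list (2 of 7) while NKG7 and IL2RB fell in the NK list (2 of 3) and CD8A and SKAP1 in the T cell list (2 of 4). In mean log2(CPM + 0.5), the NK list was at 2.78 and 3.30 in GFP control 1 and 2, the libraries with leukocyte transcripts. It was at 1.54 to 1.74 in GFP control 3 to 5 and 0.99 to 1.70 in cell-cell interaction. For the T cell list these levels were 1.91 and 2.23, 1.03 to 1.24, and 0.97 to 1.61. ITGAM rose and SPI1 fell among 5 monocyte and macrophage markers. HCLS1 rose and ITGAL and PTPN6 fell among 7 pan-leukocyte markers (median -0.52, mean -0.18, upward test). NFE2 fell among 2 erythrocyte and platelet markers, and the 1 xenoantigen synthesis gene tested did not pass. The T cell, NK, erythrocyte and xenoantigen lists had fewer than 5 tested genes and no set test.

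Leukocyte transcripts were highest in the library labelled GFP control 2, with PTPRC at 8.06 CPM and CXCR4 at 52.8 CPM, and next in GFP control 1, with 4.01 and 25.9 CPM. Cell-cell interaction 5 had 7.34 CPM of CXCR4 and 2.19 CPM of PTPRC, and the highest PTPRC level in the other 15 libraries was 0.548 CPM.

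In wild type 2 and KEC plus all cells 1, SLC34A1 was at 30.6 and 31.7 CPM, LRP2 at 20.9 and 21.0 CPM and AQP1 at 24.9 and 25.7 CPM, and the highest values in any other library were 4.81, 2.16 and 2.69 CPM. The kidney epithelial list that holds these genes did not stand apart there, with a mean log2(CPM + 0.5) of 4.66 and 4.64 against 4.15 to 4.85 in GFP control. The interferon-stimulated gene MX1 was at 40.9 and 43.4 CPM in these libraries and between 186 and 2050 CPM elsewhere. The epithelial keratin KRT8 ranged from 576 to 1522 CPM over the 18 libraries, and the endothelial adhesion molecule PECAM1 from 0.879 to 4.86 CPM. In GFP control the 13 kidney epithelial markers summed to 1755 to 2553 CPM and the 22 endothelial identity genes to 243 to 342 CPM. The endothelial name is that of the labels. These levels do not by themselves bear it out, and the cell type was not tested.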
